A study of Sesamum indicum with 12 samples.

How the data were processed

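Root RNA of 2 sesame lines was sequenced, the drought-tolerant TEX-1 and the drought-sensitive VEN-1. Seedlings 4 weeks old stood for 12 h in water (control) or in 20% polyethylene glycol 6000 (PEG), an osmotic agent that lowers the water potential around the root. Per the labels, each of the 4 groups holds 3 independent biological replicates, so 12 libraries were compared.

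The authors deposited 4 tables, 1 per group, with 1 column of FPKM (fragments scaled by transcript length and by library size) per replicate. Per the series design text, the authors checked reads with FastQC, removed adapters with Cutadapt, trimmed bases under quality 20 with FastX-toolkit and mapped with TopHat2 at default settings to the Sinbase sesame genome. Per the same text, they assembled transcripts with Cufflinks, merged them with the annotation using CuffMerge, and had Cuffquant and Cuffnorm write the FPKM with corrections for fragment bias and for reads that map to several places. That text also names CLC Genomics Workbench 4.5 for adapter removal, mapping and normalization, and does not say how the 2 descriptions go together. It names Cuffdiff for a comparison of pooled samples, and the submitters' processing notes list FastQC, cutadapt, TopHat2, Cuffdiff and DESeq2 without versions. Whether the 4 tables were normalised together is not given in the sources used here. All 4 tables list the same 28659 genes (XLOC identifiers) on 83287 transcript rows. The authors' own lists of changed genes and the metabolite measurements that the labels mention were not used here.

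Each gene carried 1 value per library, repeated on all of its transcript rows: 13844 genes had over 1 row, and the largest number of distinct values within a gene was 1. The plan had assumed that several rows per gene would hold different values to be summed. Since the rows hold a repeated gene value, 1 value per gene was used. Taking the highest row gives that same value by construction, and summed rows were run as a setting added later. No 2 libraries were identical, and no column of per-sample values was left unused.

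The depth of the libraries is unknown, because the tables hold no counts. Among single-transcript genes, FPKM times length was searched for steps of whole fragments: 20.5% to 23.0% of values of few steps lay within 0.05 of a step, against 10% by chance, so whole fragments were not recovered. No counting intervals or detection limits are given for that reason. A value of 0 is reported as listed at 0, since 11 cases of a gene at 0 in 1 library with at least 10 FPKM in the other 11 were found, such as transportin-1 in VEN-1 control 1.

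Gene descriptions came from the tables, which pair each transcript with its best match. All 20070 of the 20070 LOC symbols in them were found in the RefSeq table for sesame (assembly S_indicum_v1.0), which was used for names only. Linkage groups, starts and ends are those of the tables, on the Sinbase build. Of 19010 genes kept, 13741 had a naming description and 5269 did not. Transcripts of 662 kept genes match over 1 reference gene, 1884 kept genes share a LOC symbol with another, and 129 are under 200 bp long, so values of such genes are uncertain.

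Genes with a group mean of at least 1 FPKM in any group were kept, 19010 of 28659. The values were taken as log2(FPKM + 1), and every log2 change here is on that scale. The linear model of limma 3.58.1 with a mean-variance trend (R 4.3.3) was fitted to all 12 libraries with 4 group means, so that 1 estimate of spread per gene is shared. From it came 5 contrasts: PEG against control in each line, the difference of the responses of both lines, TEX-1 against VEN-1 in control, and TEX-1 against VEN-1 under PEG. All p-values are two-sided, from limma unless camera or fry is named, and adjusted by the Benjamini-Hochberg method. A gene is called at an adjusted p under 0.05. Errors beside FPKM are SD with n = 3.

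The choices of test, contrasts, filter, gene lists and alternatives were made before the data were examined, except where a later choice is stated. So was the rule for naming genes. For each line under PEG it takes the 10 highest and 10 lowest log2 changes among annotated genes with at least 5 FPKM in the higher group, past the threshold and changed the same way in every replicate. The last condition was taken as every PEG library lying beyond every control library of the line, since the replicates are not paired. For the difference of responses and for the lines in control it takes the 5 highest and 5 lowest by the same conditions, but the one on replicates was not applied there. For every gene list it takes the 2 members with the largest absolute log2 change in either line, if expressed at 5 FPKM or more. Of the 8 genes called between the lines only the cysteine protease XCP2 meets the rule, and the other 7 were named after their values were seen.

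Gene groups were fixed as 31 lists of words searched in the descriptions. They cover ABA synthesis and breakdown, ABA receptors and signalling, LEA proteins and dehydrins, raffinose and trehalose synthesis, proline metabolism, amino acid and GABA metabolism, aquaporins, antioxidant enzymes, class III peroxidases, and heat shock proteins and factors. They also cover cell wall loosening and synthesis, phenylpropanoid and lignin synthesis, suberin and Casparian strip, jasmonate synthesis and signalling, ethylene synthesis and response factors, auxin transport and response, cytokinin and gibberellin, and NAC, WRKY, MYB and homeobox-leucine zipper factors. The rest cover nitrogen uptake and assimilation, sugar transport and sucrose cleavage, starch breakdown, calcium signalling kinases, cytosolic ribosomal proteins, histones and cell cycle, pathogenesis-related proteins, and lipid transfer proteins, with photosynthesis genes and seed storage and oil body genes as markers of other tissue. After the values were seen, 6 lists were added: tubulins and actins, sulfate uptake and assimilation, alternative oxidase and NAD(P)H bypass, low-oxygen response genes, proteasome subunits, and autophagy genes.

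Each list was tested with camera, which asks whether its genes moved further than other genes, at a preset correlation between genes of 0.01 and again with the correlation estimated from the libraries, a form not among the choices fixed beforehand. The fry test asks whether a list's genes moved one way on balance, and its mixed form whether they changed in either direction. Neither form of fry compares the list with other genes. The correlation that camera estimated was 0.60 for ribosomal proteins, 0.46 for seed markers and 0.21 for WRKY factors, far above the preset. At the preset, camera treats the genes of such lists as nearly independent. List p-values were adjusted over 155 tests (31 lists in 5 contrasts), and those of the added lists among themselves. Members called are counted over all 19010 genes and also adjusted over the list alone.

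The fit was tested on simulated data with 200 changed genes among 19010. It recovered 41% of 2-fold and 86% of 4-fold changes for PEG in TEX-1, 27% and 85% for PEG in VEN-1, 13% and 73% for the difference of responses, 29% and 87% for the lines in control, and 40% and 82% for the lines under PEG. The calls among unchanged genes numbered 4, 6, 3, 7 and 5 in the same order.

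The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, columns rescaled to a common median or to TPM (columns of equal sum), the replicate number as a block, and leaving out each library in turn. For lists and named genes, more of these settings were run than had been fixed beforehand. Added after the data were seen were a fit without the mean-variance trend, summed transcript rows, fits to the 6 libraries of a contrast alone, a comparison of responses without VEN-1 PEG 3, and TPM for the tests of that library. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.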

Results

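The data describe roots of sesame (Sesamum indicum) in 12 RNA libraries: the drought-tolerant line TEX-1 and the drought-sensitive line VEN-1, each in water or after 12 h in 20% PEG-6000. Each of the 4 groups has 3 independent biological replicates per the labels. The deposited values are FPKM per gene, and 19010 genes reached a group mean of 1 FPKM. The depth of the libraries is not given in the sources used here. The sums of FPKM, divided by 1000, were 802, 806 and 914 in TEX-1 control, 1160, 1134 and 945 in TEX-1 PEG, 812, 922 and 868 in VEN-1 control, and 1085, 957 and 813 in VEN-1 PEG. The median kept gene had 11.7 to 13.1 FPKM per library, and the 10 most abundant genes held 7.4% to 13.7% of the sum. Libraries of a group correlated at r = 0.933 to 0.959 on log2(FPKM + 1), the scale of all log2 changes below. The first principal component (37.3% of the variance) parts PEG from control. VEN-1 PEG 3 lies at -4.9 on it, and the other VEN-1 PEG libraries at 41 and 39.3.

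**Figure D1:**
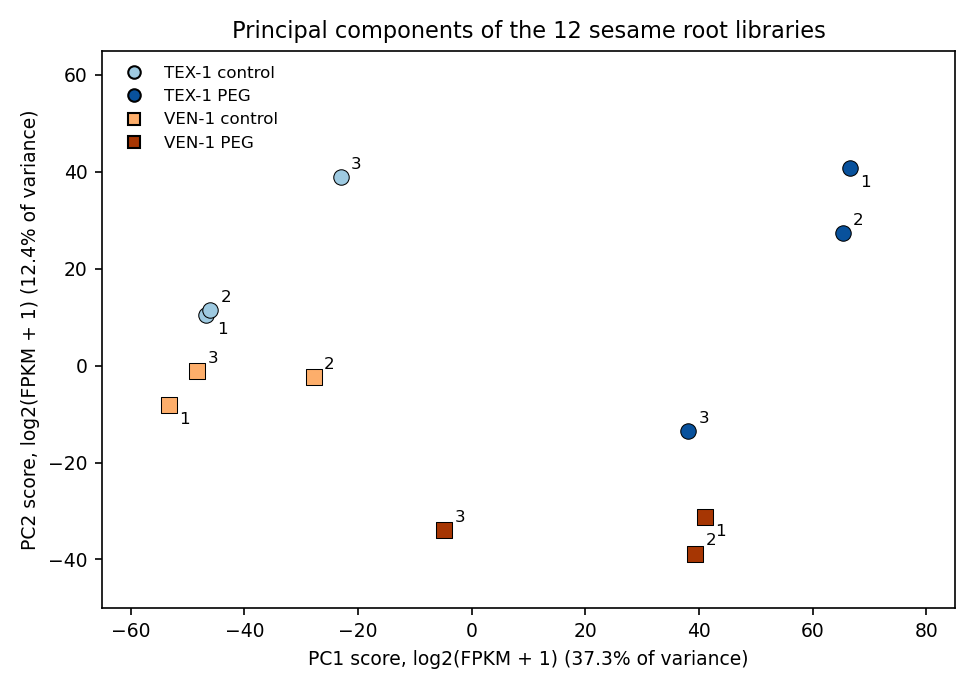
Scores of the 12 libraries on principal components 1 (x axis, 37.3% of the variance) and 2 (y axis, 12.4%) of log2(FPKM + 1), coloured by line and treatment, with replicate numbers. The TEX-1 PEG libraries lie at 38.1 to 66.6 on component 1 and VEN-1 PEG 3 at -4.9, between the controls (-53.3 to -23.1) and the other VEN-1 PEG libraries (39.3 and 41). On component 2 it lies at -33.9, with the other VEN-1 PEG libraries at -31.2 and -38.8.

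PEG lowers the water potential around a root, so cells lose turgor and growth stops unless solutes are made and proteins are kept folded. The question here is which genes of TEX-1 roots changed within 12 h. Heat shock, NAC and WRKY lists moved up and cell wall, peroxidase and nitrogen lists moved down by camera at its preset correlation, none of them with an estimated correlation. A glutathione S-transferase-like gene (LOC105163152, linkage group 6, 939643 to 948823, Sinbase build) rose from 158 ± 112 to 2770 ± 1420 FPKM (mean ± SD, n = 3), a log2 change of 4.23 with an adjusted p of 0.00266. Cinnamyl alcohol dehydrogenase 1 (LOC105156006, group 2, 12802948 to 12805462) rose from 66.5 ± 15.5 to 1050 ± 525 (log2 3.88, adjusted p = 0.00177).

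Other genes among the 10 highest in TEX-1 are of several kinds. Phosphoenolpyruvate carboxylase kinase 2 (LOC105161289, group 4, 16828298 to 16830173) rose from 6.9 ± 4.3 to 176 ± 101 FPKM (log2 4.46, adjusted p = 0.0025). A BTB/POZ and TAZ domain protein 1 (LOC105157314, group 3, 5678804 to 5681095) rose from 16.6 ± 9.76 to 326 ± 188 (4.24, 0.00237), and a cytochrome P450 714C2-like gene (XLOC_019126, group 6, 18143928 to 18167179) from 4.24 ± 1.73 to 84.5 ± 28.5 (4.02, 0.000923). Plant intracellular Ras-group-related LRR protein 5 (XLOC_021937, group 7, 5966723 to 5974212) was listed at 0 in all 6 control libraries of both lines and at 209, 137 and 81.5 FPKM in TEX-1 PEG (adjusted p = 0.000179). It shares the symbol LOC105166390 with another gene, whose values are not given here. The F-box/kelch-repeat protein SKIP25-like (LOC105164976, group 6, 18722135 to 18722305) was at 0, 10.4 and 0 in control and at 152, 126 and 13.4 under PEG (4.86, adjusted p = 0.0178). This gene is under 200 bp long, so its values are uncertain. Its call is lost, at 4.25 to 4.38, without TEX-1 control 1 (0.0726), control 3 (0.0562), PEG 1 (0.0655) or PEG 2 (0.0662). The probable F-box protein At4g22030 (LOC105168599, group 8, 8783249 to 8784523) was at 0.533, 0 and 0.838 in control and at 19.3, 36.2 and 16.7 under PEG (4.07, 0.00046). Ubiquinol oxidase 2 (LOC105159718, group 1, 8902840 to 8904925), an alternative oxidase of mitochondria that is among the 10 highest in VEN-1, rose in TEX-1 from 4.44 ± 1.93 to 65.9 ± 28.6 (3.60, 0.00354).

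Genes of protein folding were among the highest. The 18.2 kDa class I heat shock protein (LOC105167110, group 7, 11163814 to 11173583) rose from 5.32 ± 5.18 to 69.8 ± 34.2 FPKM (log2 3.82, adjusted p = 0.0054). Heat stress transcription factor HSF30 (LOC105177528, group 1, 1999381 to 2005335) was at 0.187, 0 and 0 FPKM in control and at 6.45, 28.2 and 14.2 under PEG (adjusted p = 0.00383). Of 123 heat shock proteins and factors, 52 rose and 6 fell (62 and 11 adjusted over the list alone), with a median log2 change of 0.56. The list moved up further than other genes by camera (adjusted p = 8.73e-07, and adjusted p = 0.772 with an estimated correlation), and up on balance by fry (adjusted p = 0.0325). Its median is 0.22 on TPM.

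Single genes rose in TEX-1, some named for solute metabolism and others for regulation, with no link between them tested. The raffinose, proline and ABA lists did not pass camera. Galactinol-sucrose galactosyltransferase 2 (LOC105162538, group 5, 13036433 to 13042339), named by its best match for a step of raffinose synthesis, rose from 3.26 ± 0.985 to 33.9 ± 14.9 FPKM (log2 2.97, adjusted p = 0.00046). The name alone does not show that it makes raffinose. Delta-1-pyrroline-5-carboxylate synthase (P5CS, LOC105160941, group 4, 13508215 to 13518253), which makes proline, rose from 32.2 ± 5.31 to 184 ± 35.5 (2.47, 0.00157). Proline dehydrogenase 2 (LOC105177580, group 15, 2562493 to 2573409), which breaks proline down, rose too (1.59, 0.0239), a call that ends at a log2 change of 1.47 to 1.66 without TEX-1 control 1 (adjusted p = 0.0617), TEX-1 control 2 (0.0759) or TEX-1 PEG 2 (0.0793). NAC domain protein 2 (LOC105176086, group 13, 1614989 to 1617457) rose from 24.1 ± 7.97 to 308 ± 163 (3.55, 0.00429). Protein phosphatase 2C 37 (LOC105160949, group 4, 13584168 to 13586665), of abscisic acid (ABA) signalling, rose from 1.78 ± 0.679 to 12.2 ± 6.4 (2.15, 0.00278).

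Genes with large falls in TEX-1 are of several kinds, and not all of the 10 lowest are given here. Peroxidase 47 (LOC105165788, group 6, 24995386 to 25001255) fell from 279 ± 53.8 to 10.8 ± 6.12 FPKM (log2 -4.67, adjusted p = 8.33e-05) and pectinesterase 7 (LOC105163348, group 6, 724756 to 726588) from 21.4 ± 6.16 to 0.683 ± 0.198 (-3.70, 0.000208). The 14 kDa proline-rich protein DC2.15-like (LOC105155831, group 2, 11580385 to 11580768) fell from 1030 ± 129 to 99 ± 29.5 (-3.41, 0.000597), tubulin beta-3 (LOC105164095, group 6, 8376967 to 8379427) from 315 ± 27.8 to 48.8 ± 7.12 (-2.67, 8.33e-05) and xyloglucan endotransglucosylase/hydrolase 8 (LOC105175376, group 12, 3470658 to 3472417) from 18.8 ± 1.33 to 2.29 ± 0.337 (-2.59, 0.000847). An L-ascorbate oxidase homolog (XLOC_009919, group 2, 2699155 to 2704090) fell from 53.4 ± 10.8 to 6.36 ± 1.56 (-2.89, 0.000179). An aspartyl protease family protein (XLOC_000339, group 1, 961942 to 967297) was at 63.7, 38.9 and 32.5 in control and at 0, 3.72 and 10.7 under PEG (-3.54, 0.00885). Calmodulin-like protein 3 (LOC105163780, group 6, 5060296 to 5060520) was at 14.8, 21.5 and 11.7 and at 0, 4.81 and 0 (-3.20, 0.0152), a call lost without TEX-1 control 2 (-2.98, 0.0531) or PEG 1 (-2.78, 0.0565). Among list members, the aquaporin TIP4-1 (LOC105156097, group 1, 1619531 to 1621361) fell from 291 ± 13.5 to 89.5 ± 21.7 (-1.72, 0.00182). The nitrate transporter NPF6.3 (LOC105155830, group 2, 11548003 to 11552139) fell from 26.1 ± 10.2 to 6.59 ± 1.62 (-1.79, 0.00345).

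Cell wall, peroxidase and nitrogen lists moved down in TEX-1, whereas the histone and cell cycle list and the auxin list did not pass camera. Of 185 cell wall genes 12 rose and 45 fell (17 and 49 adjusted over the list alone, median log2 change -0.26, camera adjusted p = 0.00476, and adjusted p = 0.772 with an estimated correlation). The camera call for the cell wall ends without a filter (adjusted p = 0.0555) and on TPM (0.0858). Of 39 class III peroxidases 1 rose and 11 fell (1 and 12 adjusted over the list alone, -0.47, 0.00064, and adjusted p = 0.772 with an estimated correlation). Of 58 nitrogen genes 5 rose and 16 fell (5 and 17 adjusted over the list alone, -0.27, 0.00673, and adjusted p = 0.772 with an estimated correlation), a camera call that ends without a filter (0.083). The cell wall median is -0.15 without TEX-1 PEG 1, with the call kept, and -0.11 with a pseudocount of 5. The peroxidase median is -0.28 with that pseudocount, -0.27 without a filter and -0.76 on TPM, and the nitrogen median -0.14 with that pseudocount and -0.61 on TPM.

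Of the 4 transcription factor lists, NAC and WRKY moved up in TEX-1, and MYB and homeobox factors did not pass camera. Of 51 NAC factors 17 rose and 2 fell (23 and 2 adjusted over the list alone, median 0.57, camera adjusted p = 0.000687, and adjusted p = 0.772 with an estimated correlation). Of 62 WRKY factors 14 rose and 1 fell (16 and 2 adjusted over the list alone, 0.41, 0.00723, and adjusted p = 0.8 with an estimated correlation), and the WRKY camera call ends without TEX-1 PEG 2 (median 0.31, adjusted p = 0.076). On TPM, where all genes shift down, the NAC median is 0.26 and the WRKY median 0.03, with both called, and without a filter the NAC median is 0.32. WRKY71 (LOC105167312, group 8, 602076 to 603636) rose (log2 1.99, adjusted p = 0.0135), with the call lost without TEX-1 control 2 (1.61, 0.0525) or TEX-1 PEG 2 (1.62, 0.0551). The jasmonate repressor TIFY 10a (LOC105161945, group 5, 3980395 to 3981319) rose from 244 ± 87.9 to 856 ± 313 FPKM (1.81, 0.0151), with the call lost without TEX-1 control 2 (1.53, 0.0594) or TEX-1 PEG 2 (1.53, 0.0611).

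The lists for hormones, solutes and other regulators below did not pass camera in TEX-1. Members that rose and fell, with adjusted p of camera, were 2 and 0 of 10 for ABA synthesis (0.472), 6 and 4 of 35 for ABA receptors (0.346), 2 and 0 of 20 LEA proteins (0.0913), 8 and 3 of 30 raffinose and trehalose genes (0.291), 2 and 0 of 8 proline genes (0.21) and 6 and 1 of 29 amino acid and GABA genes (0.363). For the same lists adjusted over the list alone they were 2 and 0, 6 and 4, 2 and 0, 8 and 3, 2 and 0, and 6 and 1. Jasmonate had 10 and 3 of 26 (0.0597; 13 and 5 adjusted over the list alone), ethylene 26 and 6 of 123 (0.137; 30 and 8), antioxidant enzymes 11 and 3 of 52 (0.347; 13 and 3), MYB factors 10 and 4 of 65 (0.243; 12 and 4), homeobox-leucine zipper factors 8 and 1 of 39 (0.19; 8 and 2), and cytokinin and gibberellin genes 9 and 5 of 65 (0.444; 9 and 5). By fry, which depends on the scaling, the proline, amino acid and GABA, and homeobox lists moved up on balance (adjusted p = 0.0325 each), but on TPM their medians turn from 0.31, 0.05 and 0.22 to -0.02, -0.20 and -0.03. Some of these lists pass camera in other settings. Jasmonate passes without TEX-1 control 1 (adjusted p = 0.04), control 3 (0.0265) or PEG 1 (0.0108) and on TPM (0.0192). LEA proteins pass without TEX-1 control 1 (0.0368) or PEG 3 (0.0312) and on TPM (0.0186), and ethylene genes without TEX-1 control 3 (0.0265).

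The remaining lists of TEX-1 did not pass camera either. Phenylpropanoid genes rose in 11 and fell in 17 of 85 (camera adjusted p = 0.124; 12 and 23 adjusted over the list alone), suberin genes in 2 and 6 of 35 (0.18; 2 and 7) and calcium kinases in 10 and 12 of 82 (0.573; 10 and 13). Pathogenesis-related proteins had 11 and 7 of 96 (0.826; 10 and 6 adjusted over the list alone), lipid transfer proteins 1 and 3 of 32 (0.913; 1 and 3), photosynthesis markers 4 and 1 of 28 (0.0815; 4 and 1) and seed markers 3 and 0 of 13 (0.247; 4 and 0). Starch breakdown had 0 and 0 of 15 (0.74; 0 and 0 adjusted over the list alone). For 5 lists median and mean differ in sign: auxin (median -0.04, mean 0.11; 13 and 8 of 93; 0.934; 15 and 11 alone), sugar transport (-0.05, 0.07; 5 and 3 of 37; 0.895; 5 and 3 alone), ribosomal proteins (-0.02, 0.02; 3 and 2 of 184; 0.861; 0 and 0 alone), histones (-0.08, 0.01; 15 and 14 of 103; 0.661; 16 and 14 alone) and aquaporins (0.10, -0.06; 2 and 3 of 29; 0.865; 2 and 3 alone). In other settings camera also calls photosynthesis markers without TEX-1 PEG 3 (adjusted p = 0.00797) and on TPM (0.0186), phenylpropanoid genes with a filter at 5 FPKM (0.0334) and, downward, ribosomal proteins on TPM (0.00549).

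In total limma called 3740 of 19010 genes in TEX-1 (19.7%), 2064 higher and 1676 lower, of them 1088 and 781 by at least 2-fold. The balance depends on the scaling: on TPM 1009 genes rose and 3286 fell, with the median of all genes at -0.29 against 0.01. Under TPM the medians turn from up to down for ABA synthesis, ABA receptors, proline, amino acid and GABA, aquaporin, antioxidant, ethylene, cytokinin and gibberellin, MYB, homeobox, starch, pathogenesis-related and lipid transfer lists. The count falls by over 1.5 times without TEX-1 control 1 (1749), TEX-1 control 2 (2146), TEX-1 PEG 1 (2427) or TEX-1 PEG 2 (2032). Log2 changes of genes at low FPKM depend on the pseudocount by construction. Of 76 named genes called in TEX-1, 60 stay called without each library in turn.

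In the drought-sensitive VEN-1, the same stress could meet another set of genes or a weaker answer. The question is which genes changed in VEN-1 roots under PEG. As lists, heat shock genes moved up and cell wall and nitrogen genes down by camera at its preset correlation, and the raffinose and ABA lists did not pass. Each of the 3 calls is lost at adjusted p = 0.772 with an estimated correlation. Galactinol-sucrose galactosyltransferase 2 (LOC105162538) rose from 3.53 ± 0.291 to 36.7 ± 11.6 FPKM (log2 3.01, adjusted p = 0.000746) and protein phosphatase 2C 37 (LOC105160949) from 1.06 ± 0.418 to 8.02 ± 2.33 (2.11, 0.00765). The 17.3 kDa class I heat shock protein (LOC105167111, group 7, 11174957 to 11175749) was at 0.266, 0.592 and 1.31 FPKM in control and at 35.2, 24.1 and 7.35 under PEG (3.56, 0.00304). A proteinase inhibitor (XLOC_018332, group 6, 2269128 to 2270007) rose from 108 ± 58.9 to 1050 ± 604 (3.28, 0.00943), and the auxin-responsive SAUR71 (LOC105175082, group 12, 2125572 to 2125937) from 15.6 ± 10.6 to 96.5 ± 26.2 (2.72, 0.00517).

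Some VEN-1 calls are lost without single libraries or in a fit to the 6 VEN-1 libraries, though the log2 change stays close. The glutathione S-transferase-like gene (LOC105163152) rose from 264 ± 153 to 1840 ± 1220 FPKM (log2 2.73, adjusted p = 0.0341). The log2 change is 2.21 to 2.82 where the call is lost, without VEN-1 control 1 (0.0907), control 3 (0.118), PEG 1 (0.127) or PEG 2 (0.103), or with the 6 libraries (0.0878). Cinnamyl alcohol dehydrogenase 1 (LOC105156006) rose from 106 ± 69.2 to 779 ± 439 (2.84, 0.0129), and at 2.46 to 2.84 the call is lost without the same 4 libraries (0.0543, 0.0523, 0.0563 and 0.0533) or with the 6 (0.0721). Ubiquinol oxidase 2 (LOC105159718) rose from 8.56 ± 6.81 to 82.4 ± 48.9 (3.15, 0.0139), and at 2.76 to 3.15 the call is lost without VEN-1 PEG 1 (0.0615) or PEG 2 (0.0569), or with the 6 libraries (0.0786). Dehydrin DHN1 (XLOC_019557, group 6, 24534730 to 24535930) rose from 73.1 ± 22.9 to 236 ± 66.7 (1.69, 0.0388). Its log2 change is 1.46 to 1.91 where the call is lost, without control 1 (0.14), control 2 (0.0547), control 3 (0.101), PEG 1 (0.134) or PEG 2 (0.111), with the 6 libraries (0.0506) or without a filter (0.0535). A lipid-transfer protein (LOC105165362, group 6, 21002483 to 21003540) rose from 6.23 ± 1.56 to 45.4 ± 18.2 (2.64, 0.00502) and stays called without each library.

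These 7 falls in VEN-1 stay called without each library in turn. Peroxidase 47 (LOC105165788) fell from 269 ± 14.6 to 19.5 ± 6.96 FPKM (log2 -3.78, adjusted p = 0.000347), the DC2.15-like protein (LOC105155831) from 751 ± 202 to 76.1 ± 35.8 (-3.38, 0.000963) and pectinesterase 7 (LOC105163348) from 26 ± 14.2 to 1.6 ± 0.419 (-3.26, 0.000746). A 2-oxoglutarate and Fe(II)-dependent dioxygenase (LOC105160954, group 4, 13643983 to 13645997) fell from 92.6 ± 15.6 to 11.8 ± 1.97 (-2.87, 9.42e-05), a berberine bridge enzyme-like 18 gene (LOC105175812, group 12, 5675298 to 5687200) from 234 ± 40.9 to 31.5 ± 2.59 (-2.85, 0.00121), and peroxidase 16 (LOC105155705, group 2, 10275638 to 10277592) from 69.4 ± 16.6 to 11.8 ± 3.07 (-2.47, 0.000981). Tubulin beta-3 (LOC105164095) fell from 272 ± 39.6 to 56.7 ± 12.4 (-2.25, 0.000267). Other calls of falls end, such as fatty acyl-CoA reductase 3 (LOC105171054, -1.33, adjusted p = 0.0281) without VEN-1 control 1 (0.0804), control 2 (0.0747), control 3 (0.0858), PEG 1 (0.11) or PEG 2 (0.0965), and TIP4-1 (LOC105156097, -1.31, 0.0118) without control 1 (0.0526).

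Camera called 8 lists in VEN-1. Heat shock proteins rose in 29 and fell in 2 of 123 (50 and 4 adjusted over the list alone, median log2 change 0.43, and adjusted p = 8.72e-07, and adjusted p = 0.772 with an estimated correlation). LEA proteins rose in 3 of 20 (8 and 0 adjusted over the list alone, 0.62, 0.00454, and adjusted p = 0.772 with an estimated correlation). Cell wall genes rose in 4 and fell in 27 of 185 (7 and 37 adjusted over the list alone, -0.25, 0.000754, and adjusted p = 0.772 with an estimated correlation), and nitrogen genes in 1 and 10 of 58 (3 and 14 adjusted over the list alone, -0.34, 0.000966, and adjusted p = 0.772 with an estimated correlation). Ribosomal protein genes lay higher in 169 of 184, with 5 called (0 adjusted over the list alone, 0.35, 3.92e-10, and adjusted p = 0.8 with an estimated correlation). Without VEN-1 PEG 1 the ribosomal median is 0.15, with that library at 0.75 and the other VEN-1 PEG libraries at 0.18 and 0.15. The LEA median is 0.33 without VEN-1 PEG 1, 0.94 without VEN-1 PEG 3, 0.3 with a pseudocount of 5 and 0.13 without a filter. Without a filter the cell wall median is -0.05 and the nitrogen median -0.12, and with a pseudocount of 5 they are -0.12 and -0.22.

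The calls of the other 3 lists are lost without single VEN-1 libraries. Class III peroxidases rose in 2 and fell in 11 of 39 (2 and 13 adjusted over the list alone, median -0.32, and adjusted p = 0.00897, and adjusted p = 0.8 with an estimated correlation). The call is lost without VEN-1 PEG 2 (-0.14, 0.0627). NAC factors rose in 4 of 51 (7 and 0 adjusted over the list alone, 0.32, 0.00572, and adjusted p = 0.8 with an estimated correlation). Its call ends without VEN-1 PEG 2 (0.28, 0.0856). Lipid transfer proteins rose in 3 and fell in 1 of 32 (5 and 2 adjusted over the list alone, 0.37, 0.0444, and adjusted p = 0.8 with an estimated correlation), a call lost without VEN-1 control 1 (0.057), PEG 1 (0.211) or PEG 3 (0.144), or with a pseudocount of 0.1 (0.051), a filter at 5 FPKM (0.127) or the block (0.0595).

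Camera did not call the following lists in VEN-1. Members that rose and fell, with adjusted p of camera and the members adjusted over the list alone, were 2 and 0 for ABA synthesis (0.372; 3 and 1), 4 and 1 for ABA receptors (0.584; 5 and 3), 0 and 0 for proline (0.703; 0 and 0), 2 and 0 for amino acids and GABA (0.396; 2 and 0), 4 and 2 for antioxidant enzymes (0.184; 6 and 3), 9 and 6 for phenylpropanoids (0.974; 12 and 13) and 3 and 4 for jasmonate (0.934; 3 and 5). Ethylene had 5 and 6 (0.934; 5 and 6), WRKY factors 1 and 4 (0.865; 1 and 4), MYB factors 5 and 3 (0.17; 6 and 3), homeobox factors 3 and 0 (0.6; 3 and 0), sugar transport 2 and 3 (0.347; 3 and 5), photosynthesis markers 1 and 0 (0.31; 3 and 0) and seed markers 0 and 2 (0.112; 1 and 4). Seed markers pass, downward, without VEN-1 control 1 (adjusted p = 0.0322) or PEG 2 (0.0249) and with a filter at 5 FPKM (0.0372).

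The last 9 lists of VEN-1 have no clear direction, since median and mean differ in sign for 7 and the mean is 0.00 for 2. With median and mean, these are raffinose and trehalose (-0.11, 0.05; 2 and 2 called; camera adjusted p = 0.832; 5 and 3 adjusted over the list alone), aquaporins (0.03, -0.05; 1 and 2; 0.995; 2 and 3), suberin (-0.05, 0.06; 1 and 2; 0.934; 1 and 2), auxin (-0.02, 0.03; 7 and 7; 0.765; 10 and 11) and cytokinin and gibberellin (-0.01, 0.07; 1 and 4; 0.888; 1 and 4). The others are starch (0.05, -0.02; 0 and 0; 0.886; 0 and 0), calcium kinases (0.03, -0.02; 2 and 7; 0.458; 2 and 11), histones (-0.09, 0.00; 5 and 4; 0.78; 7 and 9) and pathogenesis-related proteins (-0.09, 0.00; 2 and 5; 0.509; 3 and 5).

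In total limma called 1355 of 19010 genes in VEN-1 (7.13%), 637 higher and 718 lower, of them 432 and 416 by at least 2-fold. On TPM it called 557 higher and 774 lower, with the median of all genes at -0.08, and the medians of the ABA receptor, amino acid and GABA, aquaporin, phenylpropanoid, ethylene, WRKY, homeobox, starch and calcium lists turn from up to down. The count moves by over 1.5 times without VEN-1 control 1 (403), control 2 (719), control 3 (488), PEG 1 (400), PEG 2 (465) or PEG 3 (2242), and fitted to its own 6 libraries it is 351. The balance moves with it. Without VEN-1 PEG 3 there are 1229 higher and 1013 lower, without PEG 1 there are 124 and 276, and with the 6 libraries 111 and 240. Of 47 named genes called in VEN-1, 23 stay called without each library in turn.

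**Figure D2:**
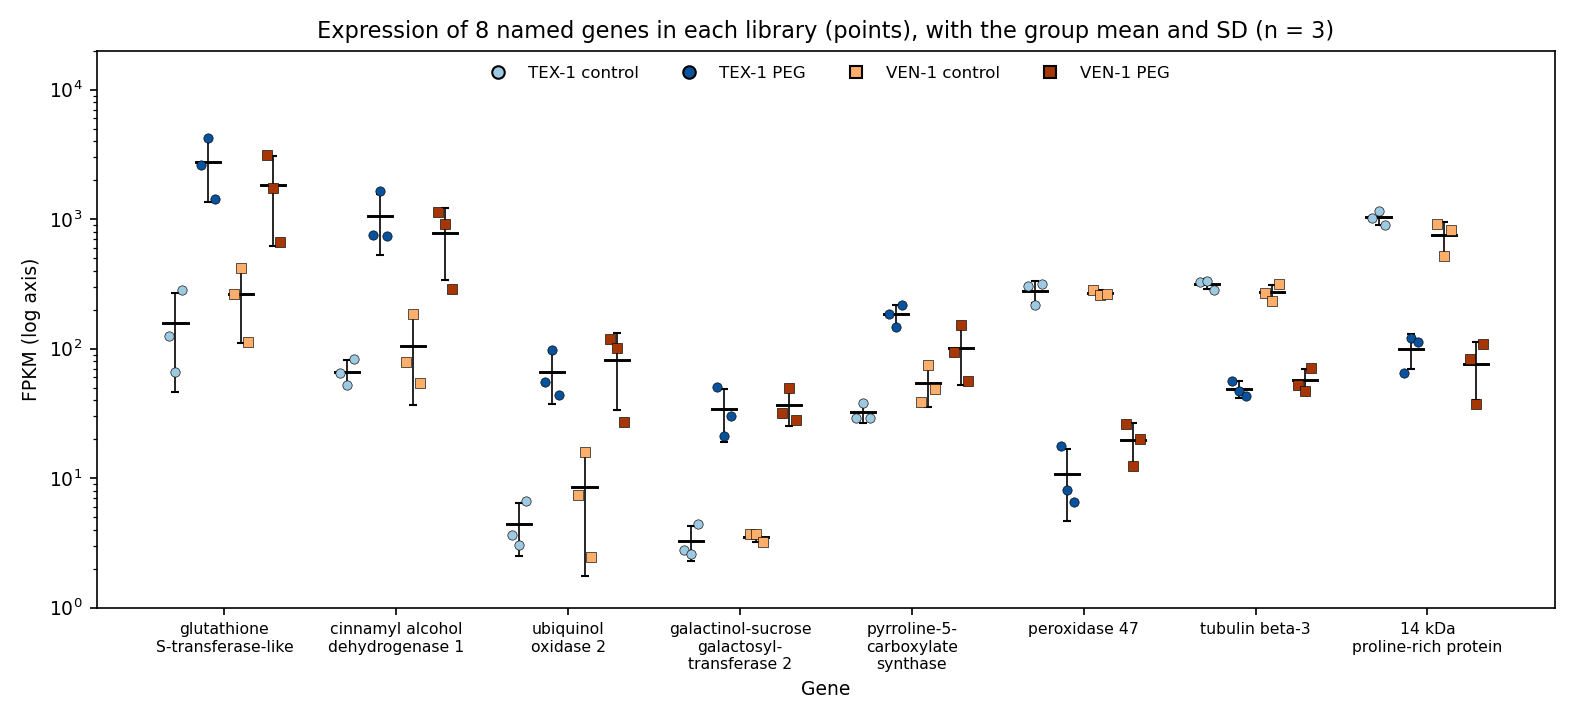
FPKM of 8 genes (log y axis) in the 4 groups of line and treatment (x axis); points are libraries, bars mean ± SD (n = 3). Galactinol-sucrose galactosyltransferase 2 rose to 33.9 in TEX-1 and 36.7 in VEN-1, and peroxidase 47 fell to 10.8 and 19.5.

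**Figure D3:**
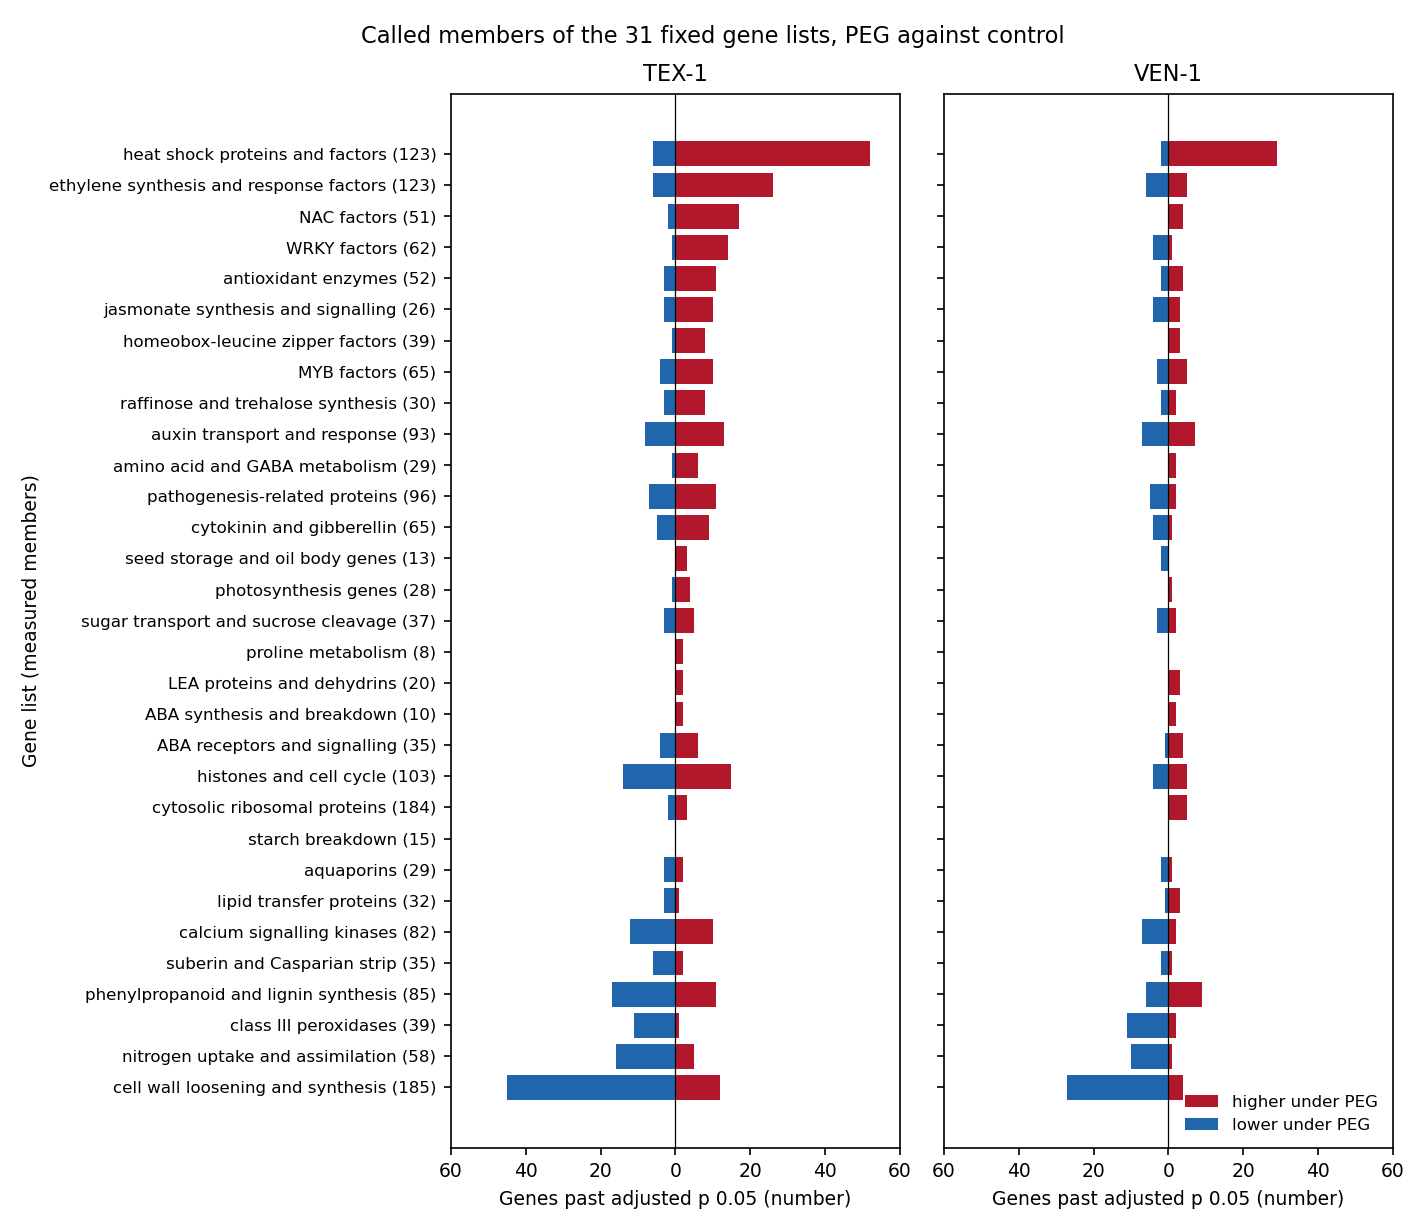
Number of called members (x axis, higher to the right and lower to the left) of 31 gene lists (y axis) under PEG in each line. Heat shock proteins had 52 higher in TEX-1 and 29 in VEN-1 and cell wall genes 45 and 27 lower. On TPM, where genes shift down, heat shock genes hold their direction, while 13 list medians in TEX-1 turn from up to down. The TEX-1 camera call for cell wall genes ends on TPM (adjusted p = 0.0858).

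A tolerant line may differ from a sensitive one by other genes or by the size of a shared response. The question is whether genes answered PEG differently in TEX-1 and VEN-1. The direction was mostly shared: of 897 genes called in both lines, 894 went the same way, 422 up and 472 down, where independent lists would share 69 and 63. The 897 become 1527 without VEN-1 PEG 3, 555 without TEX-1 control 1, and 298, 585, 360, 329 and 317 without VEN-1 control 1, control 2, control 3, PEG 1 and PEG 2. Both contrasts share 1 estimate of spread per gene, which favours calls of the same genes. With each line fitted to its own 6 libraries, 207 genes were called in both, 206 the same way. Of the genes called in TEX-1, 93.3% had the same sign in VEN-1, and the responses correlated at r = 0.64 across genes. The response was smaller in VEN-1 for 88.3% of the genes called in TEX-1 (median ratio of VEN-1 to TEX-1 0.563). Choosing the genes in 1 line favours that line, and among genes called in VEN-1 the TEX-1 response was the smaller one (median ratio of TEX-1 to VEN-1 0.866). The slope of the major axis (the first principal axis of both responses, not a regression line), VEN-1 against TEX-1, was 0.757. It ranged from 0.64 without TEX-1 PEG 3 to 0.952 without VEN-1 PEG 3, with 0.666 without TEX-1 control 3 and 0.857 without VEN-1 control 2.

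Single genes were not shown to differ in response. P5CS (LOC105160941) rose by a log2 of 2.47 in TEX-1 and changed by 0.83 in VEN-1 (adjusted p = 0.144), but the difference of 1.64 had an adjusted p of 0.498. For NAC domain protein 2 (LOC105176086) the VEN-1 change was 1.32 (adjusted p = 0.223) and the difference 2.23 (0.545), and for TIFY 10a (LOC105161945) 0.23 (0.787) and 1.58 (0.541). Without VEN-1 PEG 3, P5CS (1.19, adjusted p = 0.0274) and NAC domain protein 2 (2.12, 0.0232) are called in VEN-1 as well. The cysteine protease XCP2 (LOC105158866, group 3, 19573585 to 19579054) rose in TEX-1 from 32.9 ± 4.36 to 51.4 ± 4.8 FPKM (0.63, 0.013) and fell in VEN-1 from 87.9 ± 9.51 to 47.7 ± 3.51 (-0.87, 0.00901), a difference of 1.5 (adjusted p = 0.0763). By limma 0 genes passed the test of the difference, with 1666 at an unadjusted p under 0.05 where chance gives 950. It called 3 without TEX-1 control 1 or VEN-1 PEG 2, 2 without TEX-1 PEG 1, and 1 without TEX-1 control 2 or TEX-1 PEG 3. On simulated data, with 200 changed genes among 19010 drawn independently, the test found 13% of 2-fold differences. The share of genes that truly differ in these libraries is unknown, so the share found may differ here.

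As groups, 7 lists passed camera for the difference of responses. WRKY factors (median difference 0.34, and adjusted p = 0.000754, and adjusted p = 0.8 with an estimated correlation) and seed markers (0.99, 0.000205, and adjusted p = 0.772 with an estimated correlation) lay higher in TEX-1, and ribosomal proteins lower (-0.37, 1.77e-12, and adjusted p = 0.8 with an estimated correlation). These 3 calls hold without each library in turn, but the median differences shrink to 0.21 for WRKY factors without VEN-1 PEG 3, to 0.63 for seed markers without TEX-1 control 2 and to -0.16 for ribosomal proteins without VEN-1 PEG 1. On TPM they are 0.11 for WRKY factors and -0.61 for ribosomal proteins, and 0.29 for seed markers without a filter. Jasmonate genes lay higher in TEX-1 (0.53, 0.00454, and adjusted p = 0.772 with an estimated correlation). The call is lost without TEX-1 PEG 2 (0.32, 0.0532).

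The other 3 lists depend on single libraries. Phenylpropanoid genes lay lower in TEX-1 (median difference -0.16, and adjusted p = 0.0256, and adjusted p = 0.8 with an estimated correlation). Its call ends without TEX-1 control 1 (0.115), TEX-1 PEG 2 (0.076), VEN-1 control 3 (0.164), VEN-1 PEG 1 (0.0702) or VEN-1 PEG 3 (0.0814), without a filter (0.115) or on TPM (0.0958). Ethylene genes lay higher (0.24, 0.0414, and adjusted p = 0.8 with an estimated correlation), a call lost without TEX-1 control 1 (0.141), TEX-1 control 2 (0.302), TEX-1 PEG 2 (0.114), VEN-1 control 2 (0.101), VEN-1 PEG 1 (0.0627) or VEN-1 PEG 3 (0.084), or without a filter (0.12), with a pseudocount of 5 (0.0533) or with the block (0.0596). Lipid transfer proteins lay lower (-0.37, 0.0168, and adjusted p = 0.772 with an estimated correlation). The call is lost without TEX-1 control 2 (0.0581), TEX-1 PEG 3 (0.0963) or VEN-1 PEG 1 (0.172), or on TPM (0.0532). Adjusted over the list alone, seed markers had 4 higher and 1 lower, lipid transfer proteins 0 and 1, and the other 5 lists 0 and 0.

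Further lists pass camera for the difference of responses only in other settings. Raffinose and trehalose genes, higher in TEX-1, pass without TEX-1 control 1 (adjusted p = 0.0142), TEX-1 PEG 1 (0.0137), VEN-1 control 3 (0.0423) or VEN-1 PEG 2 (0.0116), with a filter at 5 FPKM (0.00621) and on TPM (0.032). Suberin genes, lower, pass without TEX-1 control 3 (0.0173), TEX-1 PEG 1 (0.0332) or VEN-1 PEG 2 (0.0432), and class III peroxidases, lower, without TEX-1 PEG 1 (0.00289). NAC factors pass without VEN-1 PEG 2 (0.0331), with a filter at 5 FPKM (0.0349) and on TPM (0.029), and sugar transport without TEX-1 control 1 (0.0371). Photosynthesis markers pass with a filter at 5 FPKM (0.0261) and pathogenesis-related proteins on TPM (0.0468).

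**Figure D4:**
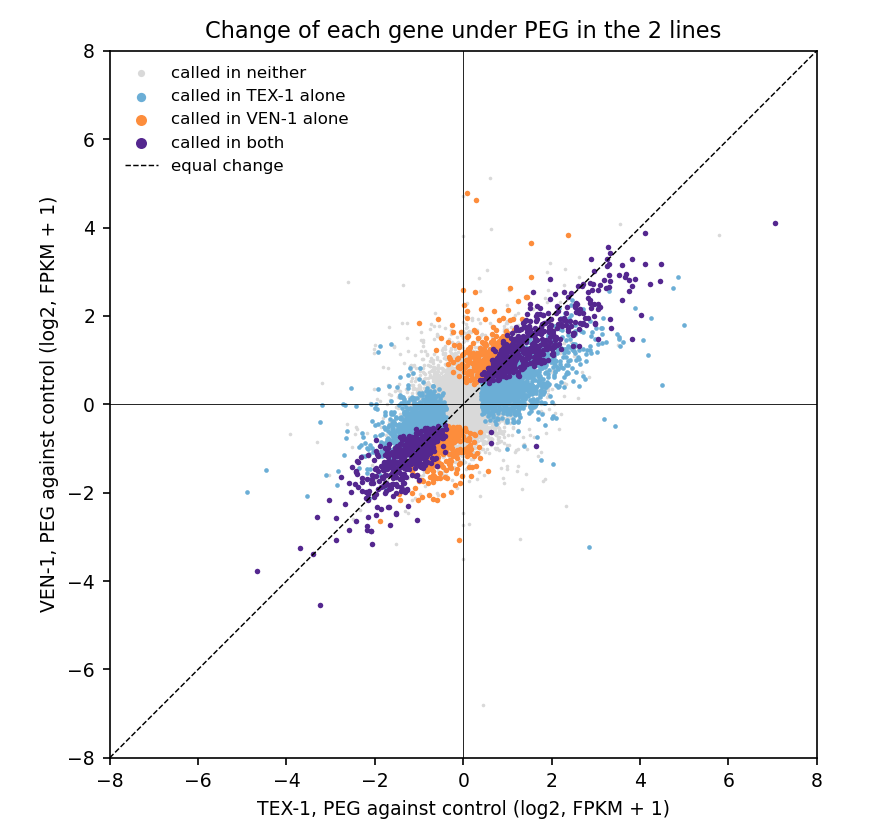
Log2 change under PEG in TEX-1 (x axis) and in VEN-1 (y axis) of 19010 genes on log2(FPKM + 1), coloured by the line in which they were called, with a dashed line of equal change. Of 897 genes called in both lines 894 went the same way, and the slope of the major axis (not drawn) is 0.757.

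Lines can also differ before any stress, in genes that prepare a root for drought. The question is which genes differed between TEX-1 and VEN-1 in water. Only 2 genes were called by limma, 1 higher and 1 lower in TEX-1, with 1213 at an unadjusted p under 0.05. An unannotated gene (XLOC_017204, group 5, 18637834 to 18640233) was at 5.06, 9.99 and 13.8 FPKM in TEX-1 control and listed at 0 in all 6 VEN-1 libraries (adjusted p = 0.00123, and 0.249 in a fit to the 6 control libraries). XCP2 (LOC105158866), a protease of xylem cells, was lower in TEX-1 (log2 -1.40, adjusted p = 0.00659), and at -1.32 to -1.40 the call is lost on TPM (0.0886), in a fit to the 6 control libraries (0.249), or without VEN-1 control 1 (0.0711) or control 2 (0.0737). The number of called genes, 2, becomes 5 without TEX-1 control 1, 4 without VEN-1 control 3, and 1 without VEN-1 control 1 or control 2.

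Camera called 4 lists between the lines in water, and in each of them 0 members were called over all 19010 genes. Ribosomal proteins were higher in TEX-1 (168 of 184 genes, median 0.19, and adjusted p = 3.99e-16, and adjusted p = 0.8 with an estimated correlation, 0.60 for this list against the preset 0.01). Suberin genes were lower (6 of 35 higher, -0.39, 0.00064, and adjusted p = 0.772 with an estimated correlation), and so were raffinose and trehalose genes (4 of 30 higher, -0.34, 0.00152, and adjusted p = 0.772 with an estimated correlation), with 0 and 3 members adjusted over the list alone, where the other 3 lists have 0 and 0. LEA proteins were higher (0.19, 0.00538, and adjusted p = 0.772 with an estimated correlation). Its call ends without TEX-1 control 1 (0.0941) or VEN-1 control 1 (0.0618). Other lists pass only in other settings. Jasmonate genes pass without TEX-1 control 2 (0.011), VEN-1 control 1 (0.0448) or VEN-1 control 2 (0.0447) and with a filter at 5 FPKM (0.0349), and ethylene and WRKY genes without TEX-1 control 2 (0.00637 and 0.0296) or VEN-1 control 2 (0.0218 and 0.0203). Sugar transport, lower, passes without TEX-1 control 1 (0.0188) and with a filter at 5 FPKM (0.0342). Seed markers, lower, pass without TEX-1 control 1 (0.0256), TEX-1 control 3 (0.00671) or VEN-1 control 1 (0.0154), with a pseudocount of 5 (0.0411), a filter at 5 FPKM (0.00999) or medians set to 0 (0.0247), and on TPM (0.0157).

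Under PEG the lines can part where their responses add to what differed before. The question is which genes differed between TEX-1 and VEN-1 roots after 12 h of PEG. Limma called 7 genes, 2 higher and 5 lower in TEX-1, with 3294 at an unadjusted p under 0.05. XLOC_017204 was at 29.0, 32.4 and 26.9 FPKM in TEX-1 PEG and listed at 0 in VEN-1 PEG (adjusted p = 1.46e-05). A glutelin type-B 2-like gene (XLOC_024632, group 8, 17613593 to 17613841) was listed at 0 in 9 libraries and at 6.7, 3.28 and 5.65 in VEN-1 PEG (0.00286, lost with a filter at 5 FPKM, 0.0889, or in a fit to the 6 PEG libraries, 0.0623), and an unannotated gene (XLOC_012951, group 3, 22163567 to 22164603) was at 4 ± 0.561 in TEX-1 and 15.1 ± 1.75 in VEN-1 (log2 -1.69, 0.00286, lost with the 6 PEG libraries, 0.117).

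The calls of the other 4 genes are lost without single libraries, with log2 changes that stay close. An uncharacterized gene (LOC105166375, group 7, 5790571 to 5796258) was at 31.8 ± 10.8 FPKM in TEX-1 PEG and 101 ± 18.6 in VEN-1 PEG (log2 -1.66, adjusted p = 0.0211), and at -1.52 to -1.84 the call is lost without TEX-1 PEG 1 (0.0548), TEX-1 PEG 2 (0.0882), VEN-1 PEG 1 (0.059) or VEN-1 PEG 3 (0.105), on TPM (0.0618) or with the 6 PEG libraries (0.219). A G-protein beta-like gene (LOC105158050, group 3, 11515648 to 11517457) was at 20.1 ± 1.14 and 42.7 ± 5.81 (-1.04, 0.0211), and at -0.98 to -1.22 the call is lost without the same 4 libraries (0.0548, 0.0919, 0.0698 and 0.107), on TPM (0.0636), with summed transcript values (0.0618) or with the 6 PEG libraries (0.219). An uncharacterized gene (LOC105165294, group 1, 12705244 to 12706014) was at 130 ± 19.4 and 39.2 ± 4.53 (1.70, 0.0471), and at 1.51 to 1.82 the call is lost without the same 4 (0.0548, 0.148, 0.133 and 0.107), on TPM (0.0636), with a filter at 5 FPKM (0.0541), without the trend (0.0519) or with the 6 PEG libraries (0.0623). A serine/threonine kinase At5g41260 (XLOC_018685, group 6, 8432366 to 8433830) was at 0, 0 and 0.547 in TEX-1 PEG and at 4.17, 5.8 and 2.92 in VEN-1 PEG (adjusted p = 0.0181), with the call lost without TEX-1 PEG 2 (0.0597) or VEN-1 PEG 1 (0.0649), with a filter at 5 FPKM (0.0588) or with the 6 PEG libraries (0.179).

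Camera called 9 lists between the lines under PEG, and in each of them 0 members were called over all 19010 genes. Suberin genes were lower in TEX-1 (1 higher and 20 lower adjusted over the list alone, median -0.90, and adjusted p = 1.28e-05, and adjusted p = 0.772 with an estimated correlation, fry 0.0325). WRKY factors (3 and 0 alone, 0.31, 8.9e-07, and adjusted p = 0.772 with an estimated correlation), jasmonate (8 and 0 alone, 0.45, 1.88e-06, and adjusted p = 0.772 with an estimated correlation) and ethylene genes (6 and 1 alone, 0.22, 0.000271, and adjusted p = 0.772 with an estimated correlation) were higher. These 4 calls hold without each library in turn, with a WRKY median of 0.2 without TEX-1 PEG 2 and an ethylene median of 0.34 without TEX-1 PEG 3. The suberin median is -0.53 with a pseudocount of 5 and -0.14 without a filter. On TPM the medians are 0.15 for WRKY factors, 0.2 for jasmonate and 0.04 for ethylene genes.

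The other 5 lists depend on single libraries, and they too have 0 members called over all 19010 genes. Phenylpropanoid genes were lower in TEX-1 (0 and 13 adjusted over the list alone, median -0.28, and adjusted p = 0.0168, and adjusted p = 0.8 with an estimated correlation), a call lost without TEX-1 PEG 2 (0.0532), VEN-1 PEG 1 (0.066) or VEN-1 PEG 3 (0.0567), without a filter (0.083) or on TPM (0.0814). Lipid transfer proteins were lower (0 and 8 adjusted over the list alone, -0.35, 0.0336, and adjusted p = 0.8 with an estimated correlation). The call is lost without TEX-1 PEG 3 (0.183), VEN-1 PEG 1 (0.211) or VEN-1 PEG 3 (0.0628), on TPM (0.0532) or with the block (0.0573). NAC factors were higher (0 and 0 adjusted over the list alone, 0.22, 0.0116, and adjusted p = 0.8 with an estimated correlation). Its call ends without TEX-1 PEG 2 (0.0811) or VEN-1 PEG 3 (0.166). Seed markers were higher (2 and 1 adjusted over the list alone, 0.46, 0.00454, and adjusted p = 0.8 with an estimated correlation), a call lost without a filter (0.263) or VEN-1 PEG 3 (0.084). Ribosomal proteins were lower (0 and 0 adjusted over the list alone, -0.16, 0.0413, and adjusted p = 0.947 with an estimated correlation). The call is lost with medians set to 0 (0.0534) or without TEX-1 PEG 2 (0.059) or TEX-1 PEG 3 (0.989), and their median turns to 0.05 without VEN-1 PEG 1 (0.172). The number of called genes, 7, becomes 240 without TEX-1 PEG 3, 59 without VEN-1 PEG 2, 12 without TEX-1 PEG 1 and 4 without VEN-1 PEG 1. It is 4 on TPM or with a filter at 5 FPKM, 16 with a pseudocount of 5, 13 without a filter and 11 with the block.

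Further lists pass camera between the lines under PEG only in other settings. Class III peroxidases, lower in TEX-1, pass without TEX-1 PEG 1 (adjusted p = 0.000233) or VEN-1 PEG 2 (0.0277), with a filter at 5 FPKM (0.0059) and with medians set to 0 (0.0292). Photosynthesis markers pass without TEX-1 PEG 3 (0.0312) and with that filter (0.00608), ABA receptors without TEX-1 PEG 2 (0.0421), and heat shock proteins (0.0243) and aquaporins (0.0368) without TEX-1 PEG 1. Cytokinin and gibberellin genes pass without VEN-1 PEG 3 (0.0448), with that filter (0.0349) and on TPM (0.0225), and homeobox factors without TEX-1 PEG 2 (0.0342), with that filter (0.0431) and on TPM (0.0224). The medians of these last lists, 0.08 each, turn to -0.05 and -0.07 on TPM.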

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

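The tests on other splits of the libraries, the test of whether the lines respond differently, the comparison of counts without 1 TEX-1 PEG library, and the tests of VEN-1 PEG 3 on genes beyond the controls and on TPM were chosen after the results were seen. The gene lists in this part are among the 31 fixed before the data were examined.

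More genes were called under PEG in TEX-1 (3740) than in VEN-1 (1355), and VEN-1 PEG 3 lies between the controls and the other PEG libraries. That 1 library could account for part of the gap: without it the VEN-1 count is 2242. The bound written before the result, 2493 (the TEX-1 count divided by 1.5), was not reached, though it took no account of the loss from fitting fewer libraries, since TEX-1 without 1 of its PEG libraries has 2032 to 3832 calls, a comparison found only afterwards. In the same fit without VEN-1 PEG 3 TEX-1 has 4066 calls, so the gap narrows but stays, and how much of it comes from that library stays open. A different response of the lines stays open as well, since 0 genes pass that test and the highest of the other splits gives 13.

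A wrong label and a mixed sample were weighed for VEN-1 PEG 3. Its position, 47.1% of the way from the control mean to the other VEN-1 PEG libraries, lies above the VEN-1 controls (-18.8%, 27.5% and -13.1%) by less than the bound written before. A gene was counted as beyond the controls if it lay over 0.5 log2 past all other control libraries, in the direction of its TEX-1 change. Of the genes called in TEX-1, 14.2% lie beyond all controls in VEN-1 PEG 3 (15.5% on TPM), against at most 5.43% (4.57%) in a control library. For genes that fell the values are 16.8% against at most 2.21%, which argues against a control with a wrong label. For genes that rose they are 12.1% against 8.43% in VEN-1 control 2, too close for those genes alone to decide. A mixture of stressed and unstressed root needs equal shares of the change for genes that rose and fell. The shares differ by -34.1 percentage points on FPKM (-47.5 to -22 over single libraries) but by 18.2 on TPM (-5.76 to 50.4). Since the sign turns with the scaling, this test cannot tell a mixture from a weaker response, and the cause stays open.

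Ribosomal protein genes passed camera for the difference of responses (adjusted p = 1.77e-12, and adjusted p = 0.8 with an estimated correlation), with a median change in VEN-1 of 0.35. Genes matched on length and expression had a median change of 0.20 (range of 1000 draws 0.08 to 0.33), so a bias of length or expression level may account for part of it. The shift could also rest on 1 library, since without VEN-1 PEG 1 the median is 0.15. A biological difference between the lines stays open, as untested.

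Seed storage and oil body genes also passed (adjusted p = 0.000205, and adjusted p = 0.772 with an estimated correlation). The 10 basic 7S globulins have median changes of 0.85 in TEX-1 and -0.78 in VEN-1, and the other 3 members 0.22 and 0.27. Seed tissue left in some samples cannot be told apart from a response of the root, since those 3 members are few and go both ways in each line.

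Further lists passed camera for the difference of responses, with no explanation tested: phenylpropanoid (adjusted p = 0.0256), jasmonate (0.00454), ethylene (0.0414), WRKY (0.000754) and lipid transfer genes (0.0168). None passes with an estimated correlation (adjusted p = 0.772 for jasmonate and lipid transfer genes, 0.8 for the others). Apart from WRKY factors, their calls are lost without single libraries, with an adjusted p of up to 0.164 for phenylpropanoid genes (without VEN-1 control 3), 0.0532 for jasmonate (TEX-1 PEG 2), 0.302 for ethylene (TEX-1 control 2) and 0.172 for lipid transfer genes (VEN-1 PEG 1). XCP2 (LOC105158866) and the uncharacterized LOC105166375 went opposite ways in all libraries of the lines, with differences of log2 changes of 1.5 and -2.11, neither past the threshold (adjusted p = 0.0763 each).

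The 10 splits of 6 libraries into groups of 3 are too few for a share under 0.05. The real split and the highest other call 3740 and 12 genes for TEX-1, 1355 and 1 for VEN-1, 2 and 2 for the lines in control (3 splits call as many) and 7 and 3 for the lines under PEG, with 1 split as large, the real one, in the other 3 tests. For the difference of responses all 100 of 100 splits reach the real count of 0, as any split would, so that count decides nothing about chance.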

How the results depend on the processing

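Across settings, 2734 comparisons of named genes stayed on the same side of the threshold, 227 lost a call, 31 gained 1 and no called gene changed sign. For lists, judged by camera's call and direction, 2395 stayed, 52 lost a call, 63 gained 1, and 1 called list changed its camera direction. That list was ribosomal proteins between the lines under PEG, whose median went from -0.16 to 0.05 without VEN-1 PEG 1. Sizes also moved where calls stayed, and medians of lists not called on FPKM turn on TPM, as given with the results. A median can also turn where a call is gained. Between the lines under PEG, camera calls cytokinin and gibberellin genes and homeobox factors upward on TPM, with medians of -0.05 and -0.07. In control, the WRKY median goes from -0.03 to 0.05 without TEX-1 control 2 and to 0.04 without VEN-1 control 2, both called. Calls in TEX-1 (3740) ranged from 1749 to 3832 over its left-out libraries, and were 4066 without VEN-1 PEG 3 and 2845 with its 6 libraries alone. In VEN-1 they ranged from 400 to 2242 (1355) and were 351. The difference of responses gave 0 calls, 0 to 3 without a library, 1 with a pseudocount of 0.1, 2 without a filter and 1 without the trend. The lines in control gave 2, 1 to 5 without a library, 1 on TPM and 1 with 6 libraries alone. The lines under PEG gave 7, 4 to 240 without a library, 16 with a pseudocount of 5, 13 without a filter, 4 with a filter at 5 FPKM, 4 on TPM, 11 with the block and 13 without the trend. Lists called by camera numbered 34, and 27 to 41 without a library. TPM kept 2683 of the TEX-1 and 1128 of the VEN-1 calls. Higher and lower calls were 2064 and 1676 in TEX-1 against 1009 and 3286 on TPM. As a block, the replicate number gave 3255 and 1080 calls in TEX-1 and VEN-1. It does not pair the libraries: 3 of 18 pairs with the same number correlate above 0.1 (range -0.28 to 0.15), and 2 of 12 libraries correlate best with their own number. No test for outlying libraries was run within the groups of 3. Calls by size of change alone and random lists, meant for pooled values, were not run.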

Other observations

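Tubulins and actins form the cytoskeleton, and the other lists here cover sulfur use, respiration and protein turnover. These 6 lists and their genes were chosen after the values were seen. Of 25 tubulins and actins 1 rose and 13 fell in TEX-1 (1 and 15 adjusted over the list alone, median -0.55, camera adjusted p = 2.99e-05, and adjusted p = 0.152 with an estimated correlation) and 0 and 5 in VEN-1 (0 and 8, -0.39, 2.99e-05, and adjusted p = 0.152 with an estimated correlation). A tubulin alpha gene (LOC105177235) fell from 53.9 ± 11.9 to 8.51 ± 0.541 FPKM in TEX-1 (log2 -2.51, adjusted p = 0.000179) and from 53.2 ± 11.8 to 19.2 ± 3.28 in VEN-1 (-1.41, 0.00502). Of 27 sulfate genes 13 rose and 2 fell in TEX-1 (13 and 3, 0.65, 0.0028, and adjusted p = 0.332 with an estimated correlation) and 8 and 1 in VEN-1 (11 and 4, 0.33, 0.0378, and adjusted p = 0.335 with an estimated correlation). APS reductase 3 (LOC105167991) rose from 29.4 ± 19 to 390 ± 187 in TEX-1 (3.75, 0.00206) and from 41.3 ± 22.8 to 306 ± 160 in VEN-1 (2.81, 0.0141).

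Of 10 alternative oxidase and NAD(P)H bypass genes 3 rose in each line (6 and 3 adjusted over the list alone), with camera adjusted p = 0.064 in TEX-1 and 0.0378 in VEN-1 (adjusted p = 0.335 with an estimated correlation). Low-oxygen genes rose in 2 and fell in 2 of 19 in TEX-1 (2 and 3 adjusted over the list alone; 0.865) and 0 and 1 in VEN-1 (0 and 1; 0.146). Non-symbiotic hemoglobin 1 (LOC105172866) fell in both (log2 -0.80, adjusted p = 0.0137, and -0.84, 0.0235). Proteasome subunits rose in 0 and fell in 3 of 43 in TEX-1 (0 and 1 adjusted over the list alone; 0.457) and 0 and 0 in VEN-1 (0 and 0; 0.129), with a median of 0.10 there that turns to -0.02 on TPM. They pass camera for the difference of responses (-0.17, adjusted p = 0.00734, and adjusted p = 0.393 with an estimated correlation) and between the lines in water (0.07, adjusted p = 0.000114, and adjusted p = 0.335 with an estimated correlation). Autophagy genes rose in 1 of 20 in TEX-1 (0 and 0 adjusted over the list alone; 0.749), with a median of 0.07 that turns to -0.28 on TPM, and in 0 in VEN-1 (0 and 0; 0.754). Tubulins and actins pass for the difference of responses (-0.24, adjusted p = 0.0378, and adjusted p = 0.335 with an estimated correlation). Under PEG, tubulins and actins were lower in TEX-1 than in VEN-1 (-0.31, adjusted p = 0.0124), and low-oxygen (0.30, 0.00849) and sulfate genes (0.26, 0.0488) higher, each with adjusted p = 0.335 with an estimated correlation.

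Photosynthesis markers held 0.0681% ± 0.0155 of all FPKM in TEX-1 control, 0.0743% ± 0.0213 in TEX-1 PEG, 0.0765% ± 0.0155 in VEN-1 control and 0.0535% ± 0.00511 in VEN-1 PEG (SD, n = 3). Seed markers held 0.307% ± 0.12, 0.446% ± 0.089, 0.422% ± 0.0987 and 0.262% ± 0.072 in the same order.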
